A study of Rattus norvegicus with 9 samples.

How the data were processed

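Poly(A) RNA from 9 samples of rat gastric lymphatic vessel was sequenced on an Illumina instrument, per the labels' protocols. The submitters' processing notes name Bowtie2 2.2.5, HISAT2 2.2.4 and the Rnor_6.0 build, and the tool that estimated the counts is not given in the sources used here. The labels' protocols do not name a stranded kit, so overlapping and antisense genes cannot be told apart. The labels give saline as the gavage of the model group, whereas the treatment protocol gives distilled water. A group treated with omeprazole that the protocol mentions was not analysed here.

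The authors deposited estimated counts per gene for 18964 genes, with FPKM and TPM values beside them, per the file headers. Estimated counts need not be whole, and 88.8% of the deposited values were whole within a tolerance of 1e-09. The deposited FPKM values, fragments scaled by gene length and depth, served an alternative fit, and the deposited TPM values were not used in tests. A second deposited table holds the authors' log2 fold changes between groups with p-values and q-values from DESeq2, per its headers, and values from it are named as such. The direction of its fold changes, second group over first, was taken from the group averages in the same table. A further 45 columns of per-sample values, among them normalized counts and repeats of the same values, were not used here. Coordinates are those of the authors' table, on Rnor_6.0, and chromosome numbers were derived from the cytogenetic bands of the genes on each sequence. The table holds no genes of the mitochondrial genome, so the list of 13 mitochondrially encoded genes had 0 members in it.

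Libraries were assigned to 3 groups of 3 from their titles. Total estimated counts were 12978311, 13357135 and 12816286 for control replicates 1 to 3, 12313823, 12787295 and 13442210 for model, and 12859119, 12989084 and 13455701 for BXD. A floor of 3 counts corresponds to between 0.195 and 0.269 CPM in these libraries. Intervals and floors cover counting error only. Replicates of each group differed well beyond sampling noise, with a chi-square per degree of freedom of 13.5 to 49.3, so none was taken for a repeat of another.

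Estimated counts were rounded to whole numbers and filtered with filterByExpr, leaving 14643 genes. Composition was scaled by trimmed means of M-values (TMM), with factors between 0.873 and 1.15. A quasi-likelihood model with robust dispersion (edgeR 4.0.16 in R 4.3.3) was fitted to all 9 libraries with the group as the only term, which left 6 residual degrees of freedom. The biological coefficient of variation was 23.3%. Genes with a Benjamini-Hochberg adjusted p under 0.05 are referred to as called. The SE of a log2 fold change is its size divided by the square root of its F statistic. CPM values use TMM-scaled library sizes. Folds against a group at 0 counts are lower bounds against 3 counts over the group, and folds with 1 to 3 counts on one side are given from the counts with an exact 95% interval.

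Before the data were examined, the comparisons, tests, alternatives, the rule for named genes and 34 gene lists were fixed. The lists cover smooth muscle contractile proteins, smooth muscle signalling and ion channels, striated muscle, nuclear and mitochondrial genes of oxidative phosphorylation, glycolysis, the tricarboxylic acid cycle, fatty acid oxidation, adipocytes, lymphatic and blood endothelium, gastric mucosa, squamous epithelium, mesothelium, exocrine pancreas, hepatocytes, lymphocytes, macrophages, neutrophils, mast cells, erythrocytes, fibroblasts, nerve and glia, interstitial cells of Cajal, immediate early genes, heat shock, endoplasmic reticulum stress, glucocorticoid response, cytokines, interferon response, hypoxia, cell cycle, circadian clock and ribosomal proteins. Some genes belong to more than 1 list. The 32 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, which asks whether the genes of a list move one way and does not compare it with other genes. With the preset correlation 14, 19 and 10 lists passed for model against control, BXD against model and BXD against control, with an estimated correlation 0 passed in each, and with fry 12, 0 and 7. The KEGG pathways in the authors' annotation with 15 to 300 tested genes, 318 in number, were tested in the same way.

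Named genes were the 8 largest rises and 8 largest falls per comparison (5 and 5 for BXD against control) among called genes with a mean of at least 1 CPM, no overlap between the groups of 3 and a symbol that is not a placeholder. Up to 3 called members of each list with the smallest p were added, or the member with the smallest p where 0 were called. The 6 genes called in both directions with the smallest larger adjusted p and, for a comparison with fewer than 10 calls, the 10 genes with the smallest p were added too. Fewer are named in places, some genes that the rule takes are not reported here, and genes named outside the rule were chosen after their values were seen. Counts simulated from the means, library sizes and dispersions of the real genes were used to test the fit, with 200 genes changed. Of genes changed 1.5-fold, 2-fold and 4-fold it recovered 5.97%, 44.8% and 93.9% for model against control, 8.96%, 49.3% and 87.9% for BXD against model, and 4.48%, 47.8% and 89.4% for BXD against control, with 7, 4 and 3 unchanged genes called among 14505, 14495 and 14496 tested. Far more than 200 genes were called in the real comparisons with control, so these shares do not measure power there.

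Reversal was set beside 40 simulations of unchanged groups and 40 in which model and BXD had the same means and control its own. The alternatives were other scalings, no filter and a stricter one, DESeq2 1.42.0, limma-voom with sample weights, a fit of the compared groups alone, replicate number as a block, a 2-fold minimum, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the 50 most abundant genes or genes of other tissues left out, and each library left out in turn. Covariates for adipocyte and striated muscle transcripts, the removal of BXD replicates 1 and 3 together and a fit without robust estimation were added after the data were seen.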

Results

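Messenger RNA was sequenced from gastric lymphatic vessels of male Sprague-Dawley rats, the collecting vessels that carry lymph away from the stomach wall. The 9 libraries formed 3 groups of 3. Control rats were fasted for 12 h and received a gavage of water. Model rats were fasted in the same way, stood in water 15 cm deep at 22 °C for 4 h, a procedure that produces gastric ulcers, and received a control gavage 30 min later. BXD rats went through the same stress and received Banxia Xiexin decoction, a Chinese herbal decoction, by gavage at 10 ml per kg. The study had 6 rats in each group, and the labels do not tie the libraries to individual rats, so p-values measure the spread between these libraries. Totals ran from 12313823 counts in model replicate 1 to 13455701 counts in BXD replicate 3, and 14643 genes were tested. On the first principal component of log2 CPM (counts scaled to library size and composition), which held 41.8% of the variance, the control libraries lay between -64.4 and -57.3 and the other 6 libraries between 14.8 and 52.7. The second component held 20.03% and set BXD replicates 1 and 3, at -55.3 and -42.7, apart from BXD replicate 2 at 4.98.

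The comparison of model with control asked what the stress procedure changed in the vessels. Transcripts of energy metabolism and of fat cells were higher in the model libraries. Of the nuclear genes of oxidative phosphorylation, 64 of 73 were called higher, as were 20 of 20 genes of the tricarboxylic acid cycle, 20 of 25 of fatty acid oxidation and 19 of 24 adipocyte genes, and edgeR called 0 lower in these 4 lists. The median log2 fold changes were 0.95, 1.13, 1.17 and 1.40, and the adjusted p was 0.603 for each of the 4 with an estimated correlation. Adjusted over the list alone, the counts of genes called higher were 67, 20, 21 and 19. Ppargc1a, the coactivator that drives mitochondrial biogenesis (gene 83516, chromosome 14, 63095291 to 63190688 in Rnor_6.0), stood at 192 ± 88.2 CPM in model (SD, n = 3) and at 18.3 ± 7.75 CPM in control (SD, n = 3). Its log2 fold change was 3.39 (SE 0.38, adjusted p = 0.000523 in edgeR's quasi-likelihood test). Plin4, a coat protein of lipid droplets, was 5.65-fold higher, Adipoq, the fat cell hormone adiponectin, 3.51-fold, and Lpl, lipoprotein lipase, 5.10-fold, with adjusted p of 0.00019, 0.000579 and 0.000622. Ucp1, the uncoupling protein of brown fat, which the naming rule takes for BXD against model, stood at 3411 ± 1953 CPM in model and 716 ± 328 CPM in control (SD, n = 3). The mean log2 CPM of the adipocyte list was 9.95 ± 0.42 in model, 8.69 ± 0.27 in control and 9.24 ± 0.14 in BXD (SD, n = 3), and the 3 model libraries lay above the 3 control libraries. With that mean as a covariate in the fit, chosen after the data were seen, edgeR called 6 genes in place of 6177. The list means of the control libraries, 8.44 to 8.98, and of the model libraries, 9.63 to 10.4, did not overlap, so that fit could hardly tell the covariate from the group.

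Contractile genes of smooth muscle were lower in model, with 13 of 26 called lower and 15 adjusted over the list alone, and a median log2 fold change of -0.75 (adjusted p = 0.799 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain (gene 24582, chromosome 10, 764421 to 859184), stood at 838 ± 247 CPM in model and 1894 ± 401 CPM in control (SD, n = 3), a log2 fold change of -1.18 (SE 0.27, adjusted p = 0.00928). Lmod1, leiomodin, and Smtnl2, a smoothelin-like protein, were 2.24-fold and 2.26-fold lower, with adjusted p of 0.00215 and 0.00735. Among 37 genes of smooth muscle signalling and ion channels, 11 were called lower and 3 higher, the same numbers as adjusted over the list alone. Ryr3, a calcium release channel, was 2.99-fold lower, Gucy1b3, a subunit of the nitric oxide receptor guanylate cyclase, 2.50-fold lower, and Agtr1a, an angiotensin receptor, 1.87-fold higher. The series title names smooth muscle contraction and energy metabolism as themes, so these lists are not independent evidence of their direction. Model replicate 2 had the highest mean of the adipocyte list, 10.4, and the lowest of the smooth muscle contractile list, 6.83, both as log2 CPM. The order did not hold across groups: adipocyte means were 9.14 to 9.39 in BXD and 8.44 to 8.98 in control, and smooth muscle means 8.10 to 8.65 in BXD and 7.72 to 8.20 in control. With library size alone 20 contractile genes were called lower.

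Lymphatic endothelial genes went both ways. In the lymphatic endothelium list, 2 of 14 genes were called higher and 2 lower, also adjusted over the list alone. Over all genes tested 42.2% were called in this comparison. That share counts calls in both directions, 3161 higher and 3016 lower of 14643 genes. A list in this comparison with a smaller share called, counting higher and lower calls alike, holds no excess over that share. Such a list can still hold an excess of higher calls or of lower calls, which that share does not measure. The share over all genes was 30.3% for BXD against control and 0.0615% for BXD against model. Lyve1, a hyaluronan receptor of lymphatic endothelium, rose from 89.4 ± 3.37 CPM to 245 ± 54.7 CPM (SD, n = 3), and Prox1, the transcription factor that sets lymphatic identity, fell from 86.0 ± 16.4 CPM to 24.1 ± 8.92 CPM (SD, n = 3). Their adjusted p were 0.000484 and 0.00391. Among 19 genes of blood endothelium, 3 were called lower and 2 higher. Adjusted over the list alone, 2 were lower and 0 higher, and over all genes 5 were called lower and 0 higher with upper quartile scaling and 8 and 0 with library size alone or FPKM. Aplnr, the apelin receptor, was 9.56-fold lower and Erg, an endothelial transcription factor, 2.43-fold lower, while Flt1, a receptor for vascular endothelial growth factor, was 1.36-fold higher.

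Of 23 glucocorticoid response genes, 13 were called higher and 0 lower by edgeR, also adjusted over the list alone, with a median log2 fold change of 1.09 (adjusted p = 0.603 with an estimated correlation). The metallothioneins Mt1 and Mt2A, which bind metal ions, were 24.0-fold and 23.4-fold higher, each with an adjusted p of 0.000177, though reads of these closely related genes could be divided between them. Cdkn1a, a cell cycle inhibitor, was 7.44-fold higher. Of 17 clock genes 9 were called higher, and 10 adjusted over the list alone (adjusted p = 0.603 with an estimated correlation), and 5 higher and 2 lower with library size alone. Ciart, a repressor of the clock, was 19.4-fold higher, and Nr1d2 and Cry2 were 3.73-fold and 3.36-fold higher. The fit had no term for the hour of collection or the time without food, which 4 h of stress could shift. Neither was told apart from the stress itself. In the glycolysis list 16 of 24 genes were called higher and 2 lower, and in the hypoxia list 10 of 24 higher and 3 lower, the same numbers as adjusted over the lists alone (adjusted p = 0.603 for both with an estimated correlation). Pfkfb3, which makes an activator of glycolysis, was 5.86-fold higher, Bnip3, a mitochondrial stress protein, 4.83-fold and Hk2, hexokinase, 3.95-fold. Of 72 cytosolic ribosomal proteins 56 were called higher and 1 lower, and 64 and 1 adjusted over the list alone, with a median log2 fold change of 0.45 (adjusted p = 0.603 with an estimated correlation). That count depended on scaling, with 38 called higher with upper quartile scaling, 6 with library size alone and 11 with FPKM. Rpl12, Rpl32 and Rpl7 were 1.86-fold, 1.55-fold and 1.72-fold higher.

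Cell cycle genes were lower, with 22 of 28 called lower and 0 higher by edgeR, 24 lower and 1 higher adjusted over the list alone, and a median log2 fold change of -0.98 (adjusted p = 0.603 with an estimated correlation). Tpx2 and Cdc20, which act in mitosis, were 3.35-fold and 2.71-fold lower, and Bub1, a spindle checkpoint kinase, fell from 19.8 ± 0.193 CPM to 7.92 ± 0.457 CPM (SD, n = 3). In the nerve and glia list 10 of 19 genes were called lower and 1 higher, and 15 and 1 adjusted over the list alone (adjusted p = 0.799 with an estimated correlation). Sox10, a transcription factor of glia, was 8.15-fold lower, while S100b, a calcium-binding protein that fat cells also make, was 2.13-fold higher. In control replicate 2 the neuronal enzyme Dbh stood at 76.8 CPM against 11.2 and 1.33 CPM in the other control libraries, so this list varied within the control group. Of 30 interferon response genes 11 were called lower and 1 higher, also adjusted over the list alone (adjusted p = 0.799 with an estimated correlation), among them Ifi47 and Stat2 at 2.52-fold and 1.60-fold lower.

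In immune cell lists, 4 of 11 neutrophil genes were called higher (adjusted p = 0.603 with an estimated correlation), led by Il1r2, a decoy receptor for interleukin-1, at 6.90-fold, with Cxcr2 at 3.47-fold and Mpo at 3.15-fold. The neutrophil count was the same adjusted over the list alone. Of 23 macrophage and dendritic cell genes 6 were called higher and 1 lower (5 and 0 adjusted over the list alone, and 3 and 3 over all genes with library size alone), with Cd14, a receptor for bacterial lipopolysaccharide, 2.30-fold higher. Of 10 mast cell genes 1 was called higher (0 adjusted over the list alone), and 0 higher and 1 lower with library size alone, upper quartile scaling or FPKM. EdgeR called 0 of 28 lymphocyte, 9 erythrocyte and 16 exocrine pancreas genes, with 3, 1 and 1 higher at unadjusted p under 0.05, and DESeq2 called 3, 1 and 1 higher and limma-voom 2, 1 and 1. Model replicate 3 had the highest lymphocyte mean of the 9 libraries, 3.54 as log2 CPM, against 1.487 and 2.197 in the other model libraries. Of 26 fibroblast and matrix genes 3 were called lower (0 adjusted over the list alone), and 7 with upper quartile scaling and 13 with library size alone or FPKM, with Col1a1, a collagen chain, 1.76-fold lower. Of 6 genes of interstitial cells of Cajal 1 was called higher and 1 lower, also adjusted over the list alone, and 0 higher and 3 lower with library size alone or FPKM.

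The remaining stress lists were mixed. Of 26 immediate early genes 4 were called higher and 2 lower (2 and 1 adjusted over the list alone, and 3 and 3 over all genes with library size alone), and of 24 cytokine genes 3 higher and 3 lower (1 and 2 adjusted over the list alone). Ptgs2, the inducible cyclooxygenase, was 4.63-fold lower, and Csf3, a neutrophil growth factor, 14.2-fold higher. The fold of Csf3 is uncertain, since its control level was near the floor, at 0.112 ± 0.101 CPM (SD, n = 3). In model Csf3 stood at 1.75 ± 0.798 CPM (SD, n = 3). Of 16 heat shock genes 3 were called higher, and of 20 genes of endoplasmic reticulum stress 6 higher and 2 lower, the same numbers as adjusted over the lists alone. With upper quartile scaling the heat shock calls were 3 higher and 4 lower and those of endoplasmic reticulum stress 6 and 5, and with library size alone 1 and 7, and 5 and 6. The heat shock median was slightly negative and its mean 0.07. Genes of other tissues were called higher for 3 of 8 hepatocyte genes and 2 of 5 mesothelial genes, and lower for 1 of 3 squamous genes, also adjusted over the lists alone, and with library size alone 1 hepatocyte gene was called higher. Of 6 gastric mucosa genes 1 was called lower and of 32 striated muscle genes 1 higher and 1 lower, and 0 of either list adjusted over the list alone. Model replicate 2 had a striated muscle mean of 3.86 as log2 CPM, where the other 2 model libraries had 0.681 and 0.17.

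**Figure D1:**
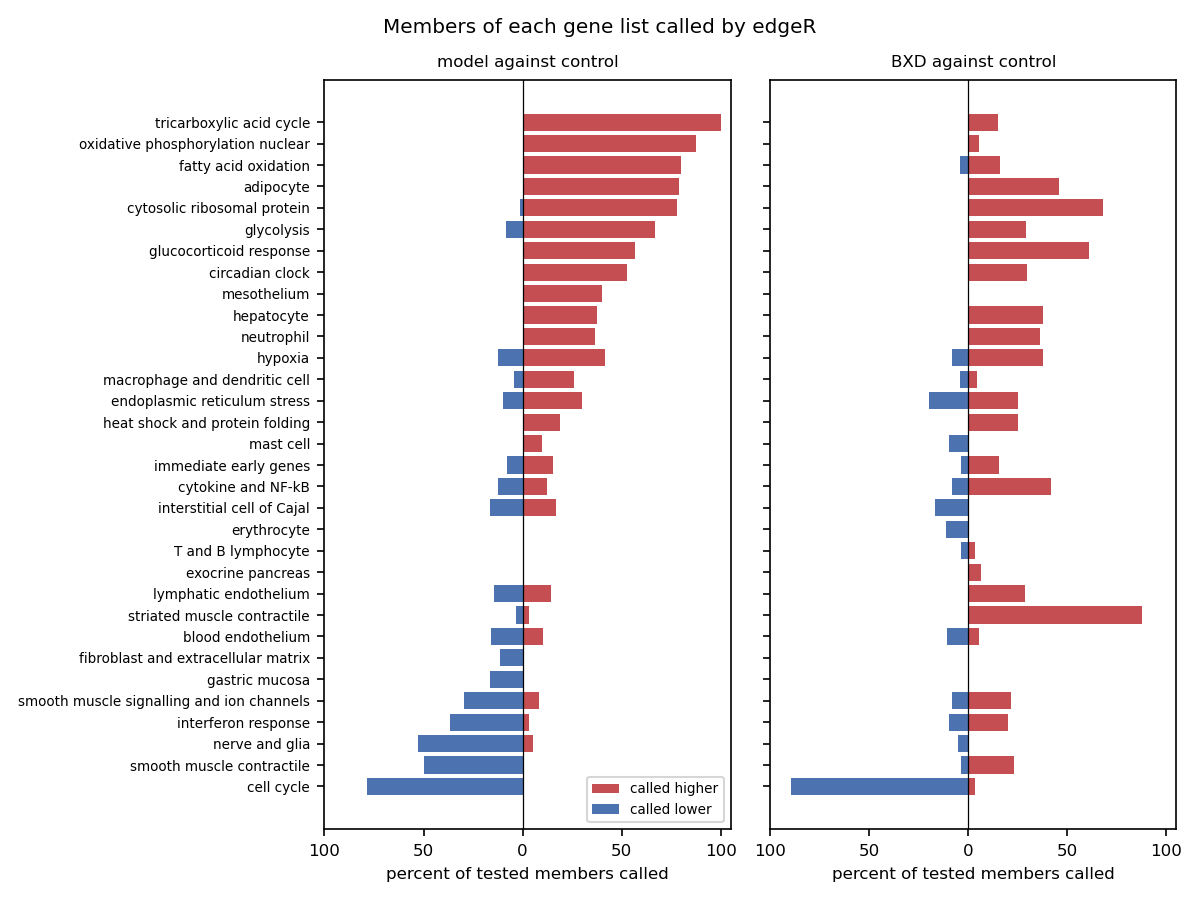
Percent of the tested members of each gene list called by edgeR (horizontal axis, higher to the right in red, lower to the left in blue) for the 32 lists with at least 5 tested members, in model against control (left) and BXD against control (right). Energy metabolism lists lead on the left, with 20 of 20 tricarboxylic acid cycle genes called higher, and on the right striated muscle leads among rises, with 28 of 32 called higher, and cell cycle among falls, with 25 of 28 called lower.

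The gene with the largest fitted rise was Elovl6, a fatty acid elongase, with 0 counts in all 3 control libraries and 11.6 ± 6.54 CPM in model (SD, n = 3), at least 163-fold higher against a floor of 3 counts over the group. Whether its 0 counts in control reflect expression or the assignment of reads was not tested. Cd209b and Glycam1, genes of lymph node sinuses and venules, were higher with most of the signal in model replicate 3, where they stood at 64.3 and 92.8 CPM. Gal, the neuropeptide galanin, was 87.5-fold higher by counts, with a 95% counting interval of 23.8 to 730, and Mfsd2a, a lipid transporter, was 53.3-fold higher (adjusted p = 0.000225). The largest fitted falls were those of Rpl30, Gtpbp6 and Robo3, with 3, 1 and 1 counts over the 3 model libraries. By counts they were 1509-fold lower (95% counting interval 516 to 7321), 224-fold lower (39.8 to 8873) and 146-fold lower (25.9 to 5808). Such switches are reported as uncertain, since a similar copy of a gene could take its reads, and no sequences were compared. The ribosomal protein gene Rpl30 was at 139 CPM in BXD replicate 1 and at 0 in the other BXD libraries. Gtpbp6 had the same pattern, with 5.59 CPM in BXD replicate 1 and 0 in the other BXD libraries. The cause of this shared pattern was not tested.

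In all, edgeR called 6177 of 14643 genes between model and control, 3161 higher and 3016 lower, and 2309 of them changed at least 2-fold, 954 higher and 1355 lower. The split depended on scaling: 51.2% of calls were higher with trimmed mean scaling, 37.7% with upper quartile scaling, 24.8% with library size alone and 25.97% with FPKM, and these scalings moved the median of all genes from -0.01 to -0.14, -0.28 and -0.22 on the log2 scale. The medians of the energy metabolism, adipocyte, smooth muscle contractile, glucocorticoid, clock, ribosomal, cell cycle, nerve and interferon lists kept their sign under each scaling, and those of the lymphatic endothelium, macrophage, cytokine, immediate early and endoplasmic reticulum stress lists turned negative with library size alone. With FPKM the median of the gastric mucosa list turned positive, and with size factors that of the heat shock list did. The authors' deposited table lists 6747 genes with a q-value under 0.05 for this comparison, 3545 higher and 3202 lower, and 5891 of them were also called here, with the same sign.

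The comparison of BXD with model asked what the decoction changed after the same stress. EdgeR called 9 genes, 8 higher in BXD and 1 lower, and the groups of 3 did not overlap for any of the 9. Csf2rb, the shared receptor chain for interleukin-3, interleukin-5 and granulocyte-macrophage colony-stimulating factor (gene 171081, chromosome 7, 119554383 to 119568248), stood at 115 ± 24.2 CPM in BXD and 32.9 ± 7.67 CPM in model (SD, n = 3), a log2 fold change of 1.80 (SE 0.20, adjusted p = 0.032). Synm, synemin, an intermediate filament protein of muscle (gene 308709, chromosome 1, 128692112 to 128722048), stood at 251 ± 18.9 CPM and 125 ± 10.7 CPM (SD, n = 3), a log2 fold change of 1.01 (SE 0.11, adjusted p = 0.032). Tmod1, tropomodulin, which caps actin filaments (gene 25566, chromosome 5, 61635244 to 61712052), was 3.08-fold higher, and Wnk2, a kinase (gene 306811, chromosome 17, 15923508 to 16032271), 3.59-fold higher. Asap3 (gene 684122, chromosome 5, 154551901 to 154596125), a regulator of Arf proteins, and Wipf3 (gene 259242, chromosome 4, 84596305 to 84676775), which binds actin regulators, were 2.31-fold and 1.94-fold higher. Id4, an inhibitor of transcription factors (gene 291023, chromosome 17, 16692557 to 16695126), was 2.31-fold higher. The uncharacterised LOC102555341 was 4.83-fold higher at a low level, 3.03 ± 0.217 CPM against 0.624 ± 0.166 CPM (SD, n = 3). Wbp11l1 (gene 103689936, chromosome 4, 170154257 to 170167724) was 7.08-fold lower, from 107 ± 12.9 CPM to 15.1 ± 4.19 CPM (SD, n = 3, adjusted p = 0.00236). Its symbol marks it as similar to Wbp11, which was at 2.00 ± 3.39 CPM in model and 77.9 ± 7.57 CPM in BXD (SD, n = 3), and is reported as uncertain because reads could be divided between both, whose sequences were not compared here. The gene with the next smallest p, Rgs2, an inhibitor of G protein signalling, had an adjusted p of 0.0558 and was not called.

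**Figure D2:**
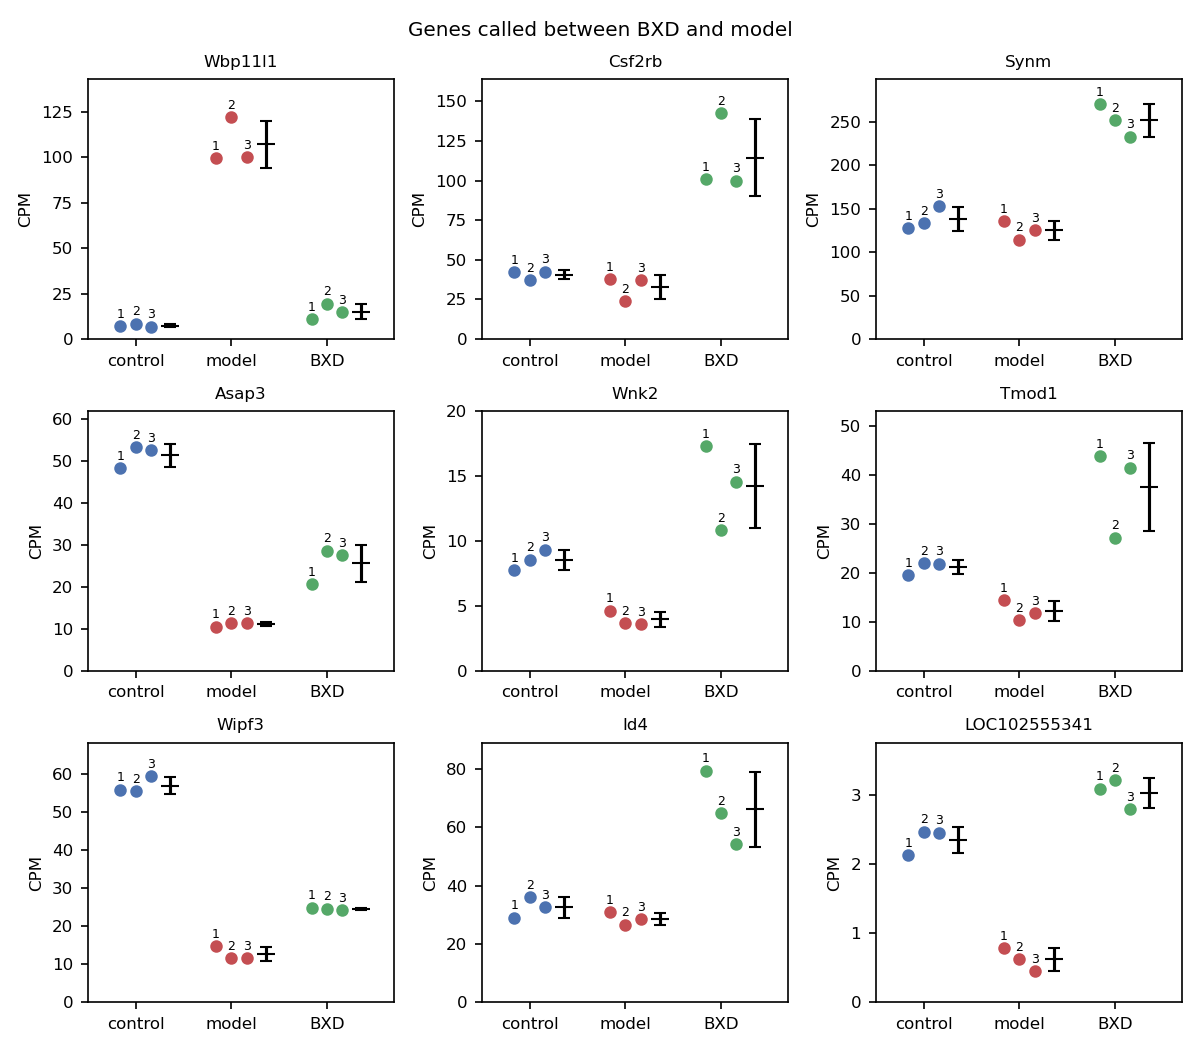
CPM of the 9 genes called between BXD and model in each library (vertical axis, CPM from 0), with replicate numbers above the points and the mean ± SD of 3 libraries as a bar beside them, for control (blue), model (red) and BXD (green). Csf2rb in BXD averages 115 CPM against 32.9 CPM in model and 40.7 CPM in control, and Wbp11l1 is high in the 3 model libraries alone, at 107 CPM on average.

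For smooth muscle contractile genes the median log2 fold change between BXD and model was 1.06. Adjusted over the list alone 23 of 26 were higher, and Synm was the 1 gene called over all genes tested (adjusted p = 0.517 with an estimated correlation). Kcnma1, a potassium channel of smooth muscle, had a log2 fold change of 1.98 (SE 0.30, adjusted p = 0.0692) and stood outside the calls. In the signalling and ion channel list 13 of 37 were higher and 3 lower adjusted over the list alone. Over all genes edgeR called 0 of them, with 15 higher and 3 lower at unadjusted p under 0.05, while DESeq2 called 11 higher and limma-voom 0 (adjusted p = 0.517 with an estimated correlation). Striated muscle transcripts were high in the same group, with a list mean of 7.25 and 6.57 in BXD replicates 1 and 3 and 1.14 in BXD replicate 2, as log2 CPM. Tmod1 was also highest in replicates 1 and 3, at 43.7 and 41.4 CPM against 27.1 CPM in replicate 2, and Synm was at 270, 251 and 232 CPM in the 3 libraries. Adjusted over the list alone, 25 of 32 striated muscle genes were higher (adjusted p = 0.623 with an estimated correlation). For oxidative phosphorylation the median was -0.63, with 58 of 73 lower and 2 higher adjusted over the list alone. For the tricarboxylic acid cycle it was -0.89, with 18 of 20 lower adjusted over the list alone, and for fatty acid oxidation -1.04, with 20 of 25. EdgeR called 0 members of these 3 lists and of the striated muscle list over all genes, with 60, 18 and 21 energy genes lower and 27 striated muscle genes higher at unadjusted p under 0.05. DESeq2 called 27, 14 and 17 energy genes lower and 14 striated muscle genes higher, and limma-voom 0 in all 4 lists (adjusted p = 0.517 for each energy list with an estimated correlation). The adipocyte median was -0.68, with 2 of 24 lower adjusted over the list alone and 0 called by edgeR over all genes, 13 lower at unadjusted p under 0.05, 6 lower with DESeq2 and 0 with limma-voom (adjusted p = 0.517 with an estimated correlation). Adjusted over the list alone 7 of 9 erythrocyte genes were lower and 1 of 19 nerve and glia genes higher, with medians of -1.03 and 1.47 (adjusted p = 0.517 for both with an estimated correlation). EdgeR called 0 of both lists over all genes, with 7 erythrocyte genes lower, 10 nerve and glia genes higher and 1 lower at unadjusted p under 0.05, DESeq2 called 7 lower and 3 higher, and limma-voom 0. Ucp1 stood at 875 ± 297 CPM in BXD (SD, n = 3), a log2 fold change of -1.96 (SE 0.49, adjusted p = 0.11). Echs1, of fatty acid oxidation, had a log2 fold change of -1.39 (SE 0.27, adjusted p = 0.0879), and Mt2A 1.16 (SE 0.28, adjusted p = 0.106). The adipocyte list mean lay between those of the control and model libraries in each BXD library, with values from 9.14 to 9.39. Other values that missed the threshold were log2 fold changes of 0.94 for Fgl2 (adjusted p = 0.0879), 1.76 for Sox10 (adjusted p = 0.0959), 0.50 for Stat2 (adjusted p = 0.0959), 1.72 for Selp (adjusted p = 0.0763) and -0.73 for Cd4 (adjusted p = 0.0959).

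At unadjusted p under 0.05, 3055 genes stood apart between BXD and model, and 3277 genes, 22.4%, had groups without overlap, where chance gives 10%. That 10% is an average over groupings of the libraries. Genes are not independent, so a single grouping can lie far from it without an effect of BXD. The share was not counted for the other groupings. The 9 calls depended on the libraries and the tool. Without BXD replicate 1 edgeR called 154 genes, without BXD replicate 2 it called 112, without model replicate 3 it called 3, and without any one of the other 6 libraries it called 1, while DESeq2 called 1107. The authors' deposited table, from DESeq2 per its headers, lists 533 genes with a q-value under 0.05, 356 higher and 177 lower, the 9 genes among them. Of 32 lists tested by camera with a preset correlation 19 passed, fry passed 0, and the lowest adjusted p with an estimated correlation was 0.517.

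Whether BXD moved the stress changes back towards control was asked with genes called in both comparisons in opposite directions, of which there were 6. That number became 122 without BXD replicate 1, 41 without BXD replicate 2, 2 without model replicate 3 and 1 without any one of the other 6 libraries, 1 with replicate number as a block or a fit of the compared groups alone, 0 with the adipocyte covariate, 11 without a filter, 12 with library size alone and 695 with DESeq2, where 49 genes had the same sign and independent lists gave 254. Asap3, Wipf3, Wnk2, Tmod1 and LOC102555341 were lower in model than in control and higher in BXD than in model, and Wbp11l1 was the reverse. Asap3 went from 51.4 ± 2.69 CPM in control to 11.1 ± 0.484 CPM in model and 25.6 ± 4.37 CPM in BXD, and Wipf3 from 57.0 ± 2.15 CPM to 12.7 ± 1.83 CPM and 24.6 ± 0.369 CPM (SD, n = 3 each). Wnk2 and Tmod1 in BXD, at 14.2 ± 3.24 and 37.4 ± 8.99 CPM, lay above their control means of 8.54 ± 0.793 and 21.1 ± 1.44 CPM (SD, n = 3). Independent lists gave 1.86 such genes. Unchanged groups simulated with the shared model libraries gave 0.025 on average, without a stress difference from which to return. A second simulation, chosen after the data were seen, kept the control means apart and gave model and BXD the same means: it gave 0.075 such genes on average and 1 at most (40 simulations), with 0.3 genes called between BXD and model on average. Across genes, which are not independent replicates, the fold changes of both comparisons had a correlation of -0.36, where unchanged groups gave -0.51 ± 0.03 and equal model and BXD means -0.21 ± 0.02 (SD, 40 simulations each). Their covariance was -0.23 against -0.08 ± 0.01 for unchanged groups, a difference of -0.15, and -0.08 ± 0.01 for equal model and BXD means. Opposite signs were seen in 68.1% of genes, against 66.9% and 55.9% in the 2 simulations, which drew genes independently. The 3 model libraries could not be split into sets of 2, so part of any excess may come from sharing them. Of the 6177 genes called between model and control, 3514 were also called in BXD against control with the same sign. The opposite sign was seen in 5. Those at least 2-fold higher in model had a median log2 fold change of -0.40 in BXD against model and 1.04 in BXD against control. Those at least 2-fold lower had 0.48 and -0.97. Both comparisons with control share its 3 libraries, which alone favours the same sign.

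The comparison of BXD with control asked how far stressed and treated vessels stood from unstressed ones. Striated muscle genes were higher, with 28 of 32 called, 29 adjusted over the list alone, and a median log2 fold change of 6.92 (adjusted p = 0.878 with an estimated correlation), and 12 called with FPKM. Myh1, a myosin of fast skeletal muscle (gene 287408, chromosome 10, 53740841 to 53764614), stood at 1376, 2.67 and 476 CPM in BXD replicates 1, 2 and 3 and at 0.318 ± 0.0951 CPM in control (SD, n = 3). Trim54 had 0 counts in control and was at least 233-fold higher, Ttn, titin, stood at 213 ± 210 CPM in BXD (SD, n = 3), and Xirp2 was 1563-fold higher by counts, with a 95% counting interval of 280 to 61761. Model replicate 2 also carried these transcripts, with Myh1 at 54.8 CPM. BXD replicates 1 and 3 stood apart for this list, and without both, chosen after the data were seen, edgeR called 2352 genes in place of 4444, in a fit that left 1 BXD library and took the spread from the other groups.

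Cell cycle genes were lower in BXD than in control, with 25 of 28 called lower and 1 higher, and 27 and 1 adjusted over the list alone (adjusted p = 0.553 with an estimated correlation). Top2a, Bub1 and Cdc20 were 2.50-fold, 2.45-fold and 3.38-fold lower. Of 23 glucocorticoid response genes 14 were called higher, 15 adjusted over the list alone (adjusted p = 0.553 with an estimated correlation), with Mt1 51.9-fold, Mt2A 52.1-fold and Cdkn1a 5.49-fold higher. Of 72 ribosomal proteins 49 were called higher, 59 adjusted over the list alone (adjusted p = 0.830 with an estimated correlation), but 11 with upper quartile scaling and 1 with library size alone or FPKM. In the cytokine list 10 of 24 were called higher and 2 lower, also adjusted over the list alone (adjusted p = 0.878 with an estimated correlation). Among them Socs3, an inhibitor of cytokine signalling, was 9.59-fold and Csf3 25.3-fold higher. Csf3 was near the floor in control, at 0.112 ± 0.101 CPM (SD, n = 3), so its fold is uncertain. It stood at 5.26, 2.43 and 1.66 CPM in BXD replicates 1, 2 and 3. BXD replicate 1 stood apart in this list: the list mean was 4.85, 3.85 and 3.02 in BXD replicates 1, 2 and 3, as log2 CPM, and 3.01 to 3.18 in control, and Socs3 stood at 349, 118 and 52.5 CPM in the BXD libraries and 18.0 ± 4.81 CPM in control (SD, n = 3). Of 11 neutrophil genes 4 were called higher and 5 adjusted over the list alone (adjusted p = 0.553 with an estimated correlation), with Il1r2 12.5-fold, S100a8 3.72-fold and S100a9 3.22-fold higher. Of 24 adipocyte genes 11 were called higher, and 13 higher and 1 lower adjusted over the list alone (adjusted p = 0.878 with an estimated correlation), with Plin4 4.00-fold and Adipoq 2.01-fold higher. In the energy lists the calls were fewer: 4 of 73 oxidative phosphorylation genes higher, 3 of 20 of the tricarboxylic acid cycle higher, and 4 higher and 1 lower of 25 of fatty acid oxidation, with Ppargc1a 4.81-fold higher. Adjusted over the list alone these were 0, 3 and 4 higher, and 1 lower (adjusted p = 0.878, 0.958 and 0.958 with an estimated correlation), and the fatty acid oxidation median of 0.12 turned to -0.08 with library size alone. Cox6a2, the muscle form of a cytochrome oxidase subunit, was 1 of the 4 and stood at 20.3 ± 18.3 CPM (SD, n = 3). In the smooth muscle contractile list 6 of 26 were called higher and 1 lower, also adjusted over the list alone (adjusted p = 0.878 with an estimated correlation), with Synm and Tpm1 each 1.82-fold higher and Smtnl2 1.94-fold lower, and 2 higher and 1 lower with library size alone. Of 14 lymphatic endothelium genes 4 were called higher, also adjusted over the list alone (adjusted p = 0.878 with an estimated correlation), with Fgl2 4.22-fold and Lyve1 2.89-fold higher, and Prox1 stood at 54.1 ± 20.5 CPM (SD, n = 3) with an adjusted p of 0.159.

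**Figure D3:**
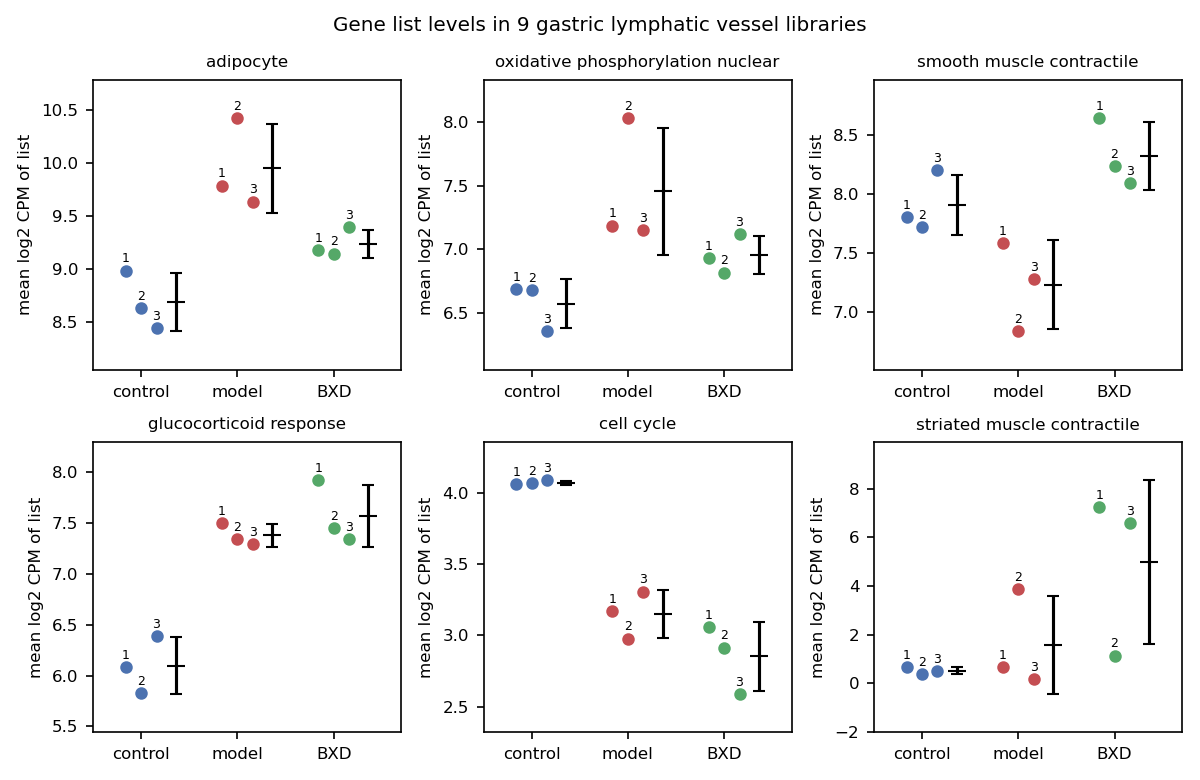
Mean log2 CPM over the tested members of 6 gene lists (vertical axes, log2 scale) in each library, with replicate numbers above the points and the mean ± SD of 3 libraries as a bar beside them, for control (blue), model (red) and BXD (green). The adipocyte mean averages 9.95 in model, 8.69 in control and 9.24 in BXD, the smooth muscle contractile mean 7.23, 7.91 and 8.33, and striated muscle is high in BXD replicates 1 and 3 and in model replicate 2.

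In all, edgeR called 4444 genes between BXD and control, 2355 higher and 2089 lower, and 1550 of them changed at least 2-fold, 765 higher and 785 lower. With upper quartile scaling 37.2% of the calls were higher, with library size alone 27.6% and with FPKM 26.1%, in place of 53.0%. The authors' deposited table lists 4919 genes with a q-value under 0.05, 2758 higher and 2161 lower, and 4178 of them were called here. Leaving out control replicate 1, 2 or 3 gave 2852, 2728 or 2813 calls.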

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

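Alternatives with an adipocyte or striated muscle covariate, without BXD replicates 1 and 3 together and without robust estimation were chosen after the data were seen. The fit without BXD replicates 1 and 3 leaves 1 BXD library and takes the spread from the other groups. The 6177 calls of model against control stayed within 1.5 times of that count in the other alternatives run, apart from 2309 with a 2-fold minimum and 6 with the adipocyte covariate. The cause was not tested. Leaving out single libraries gave 4317 to 6890. The 4444 calls of BXD against control became 1550 with a 2-fold minimum, 2370 with the adipocyte covariate, 1879 with the striated muscle covariate and 2352 without BXD replicates 1 and 3, and 2728 to 4775 with single libraries left out.

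The 9 calls of BXD against model became 1107 with DESeq2, 16 without a filter, 28 and 31 with FPKM and a pseudocount of 1 or 0.1, 2 with FPKM and no filter, 1 with the 2 groups alone, 0 with the adipocyte covariate, 3 with the striated muscle covariate and 4 without BXD replicates 1 and 3. At unadjusted p under 0.05 the edgeR fit without covariates has 3055 genes. Single libraries left out gave 1 to 154, with 154 without BXD replicate 1 and 112 without BXD replicate 2. The 6 genes called in both directions became 695 with DESeq2, 12 with library size alone, 11 without a filter, 25, 28 and 2 in the FPKM fits, 1 with the 2 groups alone, 0 and 2 with the covariates, 2 without BXD replicates 1 and 3, and 1 to 122 with single libraries left out. The cause was not tested.

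Lists passing went from 14, 19 and 10 to 0, 0 and 0 with an estimated correlation, from 19 to 0 with fry for BXD against model, and from 10 to 16 with library size alone for BXD against control. Single libraries left out gave 11 to 15, 17 to 21 and 8 to 14. Replicate numbers did not pair the libraries: same-numbered libraries had correlations of -0.43 to 0.0859, with 0 of 9 pairs over 0.1 and 0 of 9 libraries closest to their own number. With the number as a block edgeR called 5365, 1 and 3663 genes, 1 gene in both directions, and 14, 21 and 11 lists passed.

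For called named genes 0 folds reversed with other scalings of the counts, other filters, DESeq2 or limma-voom. The same held with the 2 groups alone, the replicate block or single libraries left out. Genes named as largest rises or falls had groups without overlap, so for them a reversal without a single library was hardly possible. Calls were lost more often. With single libraries left out, 56 of 81 checks of called BXD against model genes lost the call. For model against control 70 of 891 did, and for BXD against control 87 of 756. In the other settings 18 of 81 checks for BXD against model lost it. The FPKM fits, the fits with genes left out and the covariate fits were not part of these checks. With the adipocyte covariate, which separates the same libraries as the group does, the median energy fold change went from 1.03 to -0.34 on the log2 scale. For named genes that were not called, Rpl30 in BXD against model ranged from -3.31 to 12.3 on the log2 scale with single libraries left out, since BXD replicate 1 alone carries its counts, and Ctrc from -0.084 to 0.93. At this depth and n, most changes of 1.5-fold were missed in simulated data.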

Other observations

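Among the KEGG pathways of the authors' annotation, proteasome genes were called higher in model than in control for 35 of 43 and lower for 1, with a median log2 fold change of 0.47, and for 25 of 43 in BXD against control, with a median of 0.36. Of 47 genes that break down valine, leucine and isoleucine, 33 were called higher and 1 lower in model, with a median of 0.90, and 14 and 1 in BXD against control. Genes of the Fanconi anemia pathway, which repairs DNA crosslinks, were called lower for 23 of 50 in model against control and for 21 of 50 in BXD against control, with 1 higher in the latter. Of 73 genes of ribosome biogenesis 29 were called higher and 7 lower in model, and 31 and 4 in BXD. These 4 pathways were chosen after the data were seen. Over 318 pathways 55, 44 and 34 passed for model against control, BXD against model and BXD against control with a preset correlation, and 0 with an estimated one (adjusted p = 0.95 for these 4 pathways in model against control).

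All of the tests below were chosen after the results were seen. The 6 libraries of a comparison make 10 splits into groups of 3, too few for a share under 0.05. Model against control gave 6177 calls, BXD against model 9 and BXD against control 4444, each the highest of its splits (1 of 10), and the highest other splits gave 1, 0 and 0. The 6 genes called in both directions are part of the 9, so their place (1 of 10, with 0 in the next) follows from those calls and adds nothing. Passing lists were different: 6, 2 and 8 of 10 splits gave at least the 14, 19 and 10 lists of the 3 comparisons, and the highest other splits gave 18, 19 and 18. In model against control and BXD against control some regroupings thus passed more lists than the real groups, and in BXD against model 1 regrouping passed as many.

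Energy metabolism genes were higher and smooth muscle genes lower in model than in control, and both were weighed first. More adipocyte RNA in the model libraries is a candidate: within groups the mean of 22 adipocyte genes and that of the 117 energy genes deviated together over 9 libraries, with Pearson's r of 0.946 (exact permutation p = 0.00926 over 216 permutations), Spearman's rho of 0.917 (exact permutation p = 0.0139) and r of 0.902 without model replicate 2 and control replicate 1, the 1 relation tested, and with the adipocyte mean as a covariate, which separates the same libraries as the group does, the median energy fold change went from 1.03 to -0.34. The adipocyte list rose, with 19 of its 24 genes called higher in model and 0 lower, but not in every member. Pparg stood at 90.3 ± 24.1 CPM in model and 94.1 ± 22.5 CPM in control (SD, n = 3). Fasn stood at 2628 ± 731 CPM in model and 3359 ± 2157 CPM in control (SD, n = 3). Its control mean was raised by control replicate 1, at 5849 CPM against 2172 and 2057 CPM in the other control libraries. Dilution of every other cell type alike is argued against, since the smooth muscle mean fell by 0.68 on the log2 scale and those of blood endothelium and fibroblasts by 0.36 and 0.18, a difference of -0.41 (pooled SD 0.193, with no overlap of the 3 and 3 libraries, for which chance gives 10%). More fat on the dissected vessels, a response of fat cells to stress, fat that brings its own fibroblasts and vessels, and lower expression in smooth muscle cells stay open, untested.

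Striated muscle transcripts in BXD replicates 1 and 3 and in model replicate 2 were weighed next. Skeletal muscle RNA carried into some libraries, from muscle near the dissected vessel, is consistent with the values: across genes, which are not independent, the 3 libraries shared a profile, with a lowest correlation of 0.856 and a highest of 0.913. Abundant muscle genes followed, with Acta1 at 2389 and 1575 CPM and Ckm at 853 and 483 CPM in BXD replicates 1 and 3, against 21.7 and 7.85 CPM in BXD replicate 2. The libraries were picked for these same genes, and a response of the vessels could give a like profile. The correlations therefore cannot tell carried-in RNA from such a response. A response of the vessels, in all or some animals, stays open, untested.

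The swap between Wbp11 and Wbp11l1 was weighed last. Reads divided differently between the 2 genes, whose sequences were not compared, may explain it: with both genes summed, the log2 fold change of BXD against model was -0.23 (SE 0.10, adjusted p = 0.232), where Wbp11l1 alone gave -2.82. The sum stood at 52.5 ± 1.65 CPM in control, 109 ± 11.6 CPM in model and 93.0 ± 4.22 CPM in BXD (SD, n = 3), and it was called higher in model than in control, with a log2 fold change of 1.05 (SE 0.10, adjusted p = 0.000336). Why the division would differ by group was not tested.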
